A study of Mus musculus with 10 samples.

How the data were processed

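Bulk RNA of mouse liver cells and organoids was sequenced in 10 samples, 5 groups of 2 by the labels. The extract protocol describes enzymatic digestion of livers or lesions and flow sorting of YFP-positive cells. Per the submitters' processing notes the tools were STAR 2.5.4b, Subread with featureCounts, edgeR and limma, and the genome builds listed were mm9, hg19 and GRCm38, with no role given for each. Per the file headers, the authors made raw counts per gene with featureCounts v1.5.0-p3 against Ensembl release 87 on GRCm38, so coordinates here are on GRCm38. Per the file headers they counted fragments with both ends mapped, primary alignments and a mapping quality of at least 10, without using strand. Duplicates were to be ignored, but the deposited summaries hold 0 fragments flagged as duplicates, so none were removed. The deposited counts were not normalized and libraries were not pooled.

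These steps affect the measurements in several ways. Reads that map to more than 1 place have low mapping quality and are dropped, which lowers the values of genes with near-identical copies. Low mapping quality took 40.0% and 38.8% of fragments in the Ck19-derived libraries and 33.2% and 34.4% in the Sox9-derived libraries, and 52.1%, 53.5%, 59.7% and 58.4% were assigned to genes. Without strand, a gene and an overlapping antisense gene cannot be told apart. PCR copies were counted as separate fragments, so the counting intervals and the floor of 3 fragments cover counting error only.

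The deposited tables held 2 sets of count columns with the same gene models. Columns were tied to samples by name alone, before their values were looked at. The columns named Ck19 and Sox9 with a number were taken as the Ck19-derived and Sox9-derived organoids, 4 libraries in all. Columns with Sox9, a TKO tag and a number were kept as an alternative for the Sox9-derived samples. A further 4 columns matched no label and were not used. For 3 groups (6 samples) no column was matched, so the 4 planned comparisons that need them were not analysed here. The plan was 1 fit of all groups, and with the matched libraries this became a fit of 4 libraries with 2 residual degrees of freedom.

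Library totals were summed over all 49585 genes, and symbols were taken from a GENCODE table, which matched 49326 gene IDs. Genes were filtered with edgeR's filterByExpr (minimum count 10, defaults by group), scaled by TMM (factors 0.992, 1.01, 1.01 and 0.993) and tested with the quasi-likelihood functions of edgeR 4.0.16 in R 4.3.3. The Benjamini-Hochberg adjusted p threshold was 0.05, two-sided. The common biological coefficient of variation was 0.434 and the prior degrees of freedom 2.94. Means and SDs are of TMM-scaled CPM, and fold changes are Sox9-derived over Ck19-derived. The standard error of a log2 fold change is its size divided by the square root of the F statistic. For a gene at 0 in a group, the fold is a bound against 3 fragments over that group. For 1 to 6 fragments, a ratio of group totals is given where stated, with an exact binomial 95% interval. Replicate pairs were compared by chi-square per gene, which was 62.8 in the Ck19-derived and 118 in the Sox9-derived pair, far above sampling noise, so all 4 were kept as separate libraries.

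Before the data were examined, the groups, the tests, the alternatives, 20 gene lists with 394 entries and the rule for named genes were fixed. The lists cover biliary epithelial, hepatocyte, fetal liver and progenitor, bile acid and xenobiotic metabolism, Notch pathway, Wnt targets, YAP and TEAD targets, S-phase E2F targets, G2 and mitosis, interferon-stimulated, MHC class II, glycolysis and hypoxia, cholesterol synthesis, immediate early and dissociation stress, mesenchymal and stellate, endothelial, myeloid, T and NK cell, B cell and plasma cell, and erythroid genes. Named genes are Rb1, Rbl1, Rbl2, Epcam, Thy1, Krt19, Sox9, Alb and Afp in every case. To these come the 5 largest rises and 5 largest falls among called genes with a mean of at least 10 CPM, no overlap between groups and no predicted name. From each list come up to 4 called members in the direction of most called members and up to 2 in the other. Lists were tested with camera in limma 3.58.1 on log2 CPM with an inter-gene correlation of 0.01, adjusted over the lists.

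The test was tried on simulated data with the means and library sizes of the Sox9-derived against Ck19-derived comparison, with 200 of 15959 tested genes changed. edgeR recovered 16% of the genes changed 2-fold, 64% at 4-fold, 92% at 16-fold and 100% at 64-fold, with 2 false calls among 138. DESeq2 made 45 false calls among 189. Each simulated gene was given the dispersion of the trend, without spread between genes, and changed genes were taken only from those above a minimum mean count. Recovery and false calls may therefore look better than they would in these data. The alternatives were relative log expression size factors, DESeq2 1.42.0, limma-voom, no count filter beyond 1 fragment, a stricter filter (1 CPM in every library of a group and 50 fragments in total), the replicate number as a block, an estimated inter-gene correlation and leaving out each library in turn. Added after the data were seen were the TKO-tagged pair in place of the Sox9 pair, the same pair as an extra group, and a fit without genes on X and Y. Exon overlaps were measured with GenomicRanges 1.54.1, and figures were drawn with matplotlib 3.10.9.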

Results

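Gene expression was measured by bulk RNA sequencing in a mouse model of hepatocellular carcinoma (HCC) driven by loss of the Rb gene family, whose members Rb1, Rbl1 and Rbl2 restrain E2F transcription factors and cell cycle entry. Livers or visible lesions were dissociated, and cells positive for YFP, a fluorescent reporter of Cre recombination, were collected by flow cytometry. The series holds 10 samples in 5 groups of 2. Sorted liver cells make up 3 of the groups (negative for the epithelial surface protein Epcam, high in Epcam, or positive for the surface protein Thy1), and cultured organoids the others (derived from Ck19 or from Sox9 cells, as the labels put it). Ck19 is the product of Krt19, a keratin of bile duct epithelium, and Sox9 is a transcription factor of bile duct and progenitor cells. Only the organoid groups had count columns that their names tied to a sample, so the comparison reported here is Sox9-derived against Ck19-derived organoids, with n = 2 libraries in each. The labels state no purpose for this comparison beyond the origin of the cultures. The comparisons of the Epcam and Thy1 fractions with one another, and of the organoids with the Epcam-high fraction, were not analysed here.

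Fragments assigned to genes numbered 31883180 and 32747944 in the Ck19-derived libraries and 36606008 and 33154972 in the Sox9-derived libraries. At least 1 fragment was found for 27456 and 26608 genes in the Ck19-derived pair and for 22670 and 23200 genes in the Sox9-derived pair. The secreted chaperone Clu was the most abundant gene in all 4 libraries, with 1.43% and 1.66% of the fragments in the Ck19-derived pair and 2.61% and 2.11% in the Sox9-derived pair. The Pearson correlation of log2 CPM (fragments scaled to the library total) across genes, which are not independent replicates, was 0.957 within the Ck19-derived pair and 0.925 within the Sox9-derived pair. Between the groups it ran from 0.881 to 0.900. Nothing in the labels says that the libraries of a group came from separate animals or cultures. Every p-value of a single gene below thus measures only the spread between these samples, which may be technical. With the preset correlation, camera judges a list against the spread between genes, and Fisher's exact test counts genes. Neither of these p-values measures a spread between animals or cultures.

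The genes of the Rb family were read first. The series is named for their knockout, but no sample label states the genotype of the organoid libraries used here. Rb1 (ENSMUSG00000022105, chromosome 14, 73183673 to 73325822, GRCm38) was detected in every library, at 21.2 and 21.6 CPM in the Ck19-derived organoids and at 14.4 and 12.7 CPM in the Sox9-derived organoids. The difference was not called (log2 fold change −0.66, SE 0.25, adjusted p = 0.297, edgeR quasi-likelihood test). Rbl1 stood at 2.96 ± 1.58 CPM (SD, n = 2) and 2.07 ± 1.07 CPM, and Rbl2 at 7.39 ± 0.642 CPM and 8.06 ± 0.922 CPM, with edgeR adjusted p = 0.773 and 0.895. Counts summed over whole genes do not show whether particular exons were deleted, and no unrecombined control was compared, so these values do not check the knockout. Other genes share 14.9% of the exon bases of Rb1 and 20.97% of those of Rbl2, and the counting ignored strand.

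Both kinds of organoid expressed epithelial genes at high levels and little albumin. Epcam stood at 2212 ± 184 CPM in the Ck19-derived and 3257 ± 854 CPM in the Sox9-derived organoids, and Krt19 at 2200 ± 385 and 3055 ± 66.0 CPM. Neither difference was called (edgeR adjusted p = 0.312 and 0.277). Albumin (Alb) stood at 14.8 ± 8.13 and 5.29 ± 5.72 CPM and the fetal liver gene Afp at 0.296 ± 0.118 and 0.557 ± 0.787 CPM, with edgeR adjusted p = 0.526 and 0.849. Without Sox9-derived replicate 1, Alb (log2 fold change −3.55, adjusted p = 0.00879) and Epcam (0.81, adjusted p = 0.0463) were called by edgeR. Thy1 was below the count filter, with 19 fragments over the Ck19-derived pair and 1 over the Sox9-derived pair. Sox9 itself (ENSMUSG00000000567, chromosome 11, 112782224 to 112787760) was higher in the organoids named after it, at 565 ± 1.82 against 87.7 ± 14.2 CPM. That is 6.44-fold (log2 fold change 2.69, SE 0.20, edgeR adjusted p = 0.0386).

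Across 16653 tested genes, edgeR's quasi-likelihood test called 95 at a Benjamini-Hochberg adjusted p under 0.05. Of these, 31 were higher and 64 lower in the Sox9-derived organoids, and all 95 differed at least 2-fold. The smallest called log2 change was 1.44 in size, and the smallest adjusted p was 0.00895. An unadjusted p under 0.05 was reached by 2792 genes, where 833 would do so by chance. The number of calls depended on which group lost a library, more than on which library of a pair was left out. With 1 library left in a group, the spread is estimated from the other pair alone. The Sox9-derived pair varied more within itself than the Ck19-derived pair (chi-square per gene 118 against 62.8). Without Ck19-derived replicate 1 or 2 edgeR called 0 genes (1692 and 1611 at an unadjusted p under 0.05), although the log2 fold changes of called genes named here with more than 3 fragments in both groups moved by at most 0.51 (10 genes) and 0.77 (11 genes). Without Sox9-derived replicate 1 or 2 it called 1394 and 975 genes. The called genes named here were picked from these same libraries, in part for replicates that agree. Their small shifts without 1 library were therefore partly fixed by that choice. DESeq2 called 1512 genes on the same counts, among them all 95. In the simulation it made 45 false calls among 189, against 2 among 138 for edgeR. The simulated genes had no spread in dispersion around the trend, so this does not rank the tools on these data.

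**Figure D1:**
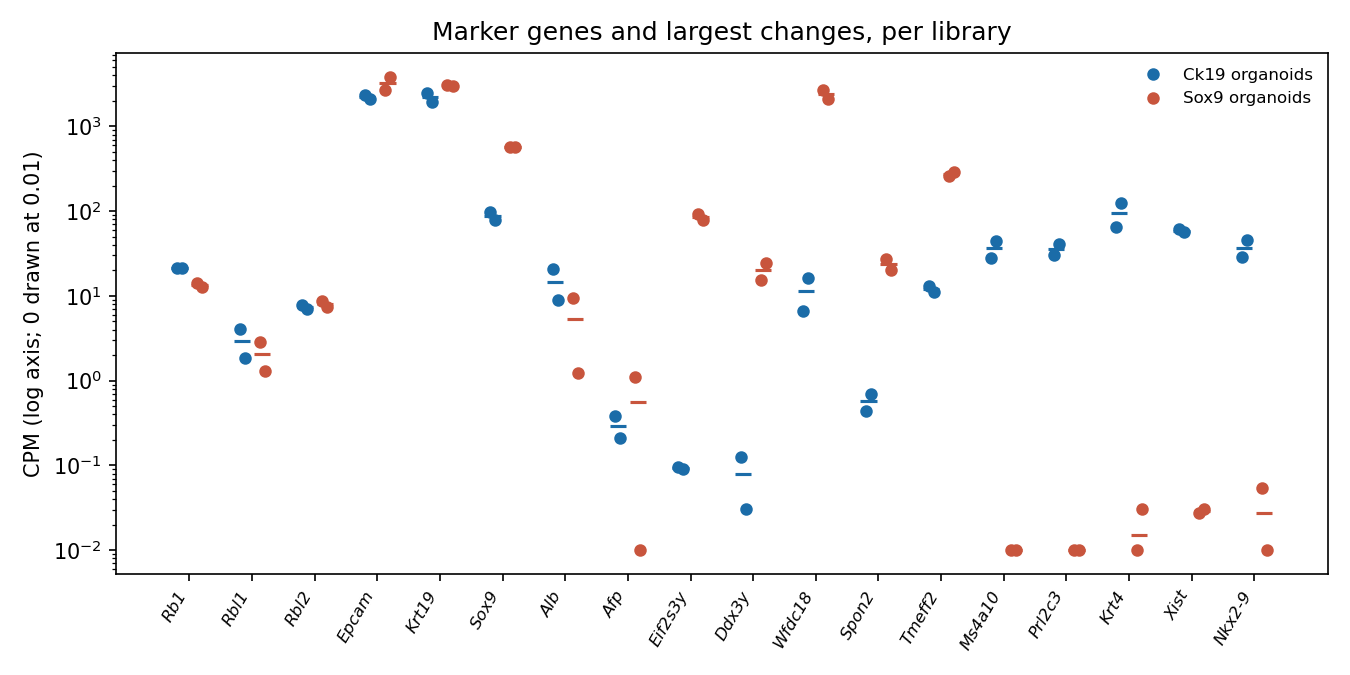
CPM on a log axis of the marker genes fixed in advance and of the largest changes, with 1 point per library, a bar at each group's mean and values of 0 drawn at 0.01. Sox9, Eif2s3y, Wfdc18, Spon2 and Tmeff2 lie higher in both Sox9-derived libraries, while Ms4a10, Prl2c3, Krt4, Xist and Nkx2-9 lie at or near 0 there.

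Among genes chosen by the fixed rule, the largest rises in the Sox9-derived organoids were in Y-linked genes and in genes of secreted or surface proteins. Eif2s3y, a Y-linked translation factor gene (chromosome Y, 1010543 to 1028847), had 5998 fragments over the Sox9-derived pair and 6 over the Ck19-derived pair (log2 fold change 9.79, edgeR adjusted p = 0.00895), and the Y-linked helicase gene Ddx3y had 1378 and 5. Xist, the RNA that silences an X chromosome in female cells (chromosome X, 103460375 to 103483217), went the other way, with 3792 fragments over the Ck19-derived pair and 2 over the Sox9-derived pair. Its ratio was 2045, with a 95% counting interval of 566 to 16890. Antisense Tsix and other genes share 12.4% of its exon bases. Xist and the 4 called Y-linked genes thus separated the groups completely in these 4 libraries. By these transcripts the Ck19-derived libraries were of female and the Sox9-derived libraries of male cells, so the groups came from different animals. Every difference between the groups reported here is therefore confounded with sex and animal, and cannot be credited to the origin of the cultures alone. With limma-voom the adjusted p of Ddx3y was 0.0568. Wfdc18, which encodes a small secreted protein of the whey acidic protein family, stood at 2385 ± 411 against 11.5 ± 6.88 CPM (207-fold, edgeR adjusted p = 0.0386). In fits without 1 library its log2 fold change ran from 7.18 to 8.46. Tmeff2, a transmembrane protein with follistatin-like and EGF-like domains, rose from 12.1 ± 1.49 to 278 ± 22.4 CPM (log2 fold change 4.52, edgeR adjusted p = 0.0213). Spon2, a secreted matrix protein, rose from 0.569 ± 0.179 to 23.6 ± 4.96 CPM (log2 fold change 5.37, edgeR adjusted p = 0.0389).

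By the same rule, the largest falls were in genes that were nearly silent in the Sox9-derived organoids. Krt4, a keratin of stratified squamous epithelium (chromosome 15, 101918536 to 101924735), stood at 95.7 ± 43.6 CPM in the Ck19-derived organoids, with 6230 fragments against 1. The ratio was 6719, with a 95% counting interval of 1205 to 265410. The homeobox gene Nkx2-9 (chromosome 12, 56611389 to 56613284) had 37.1 ± 12.0035 CPM and 2411 fragments against 2, a ratio of 1300 (359 to 10741). Ms4a10 stood at 36.3 ± 11.5 CPM and Prl2c3, a prolactin-family gene, at 35.7 ± 7.02 CPM in the Ck19-derived organoids, and both had 0 fragments in the Sox9-derived pair. With a floor of 3 fragments over the group they were at least 848-fold and at least 832-fold lower there. The Prl2c3 value is uncertain because reads that match its near-identical neighbour Prl2c2 equally well were dropped. In these genes edgeR's adjusted p ran from 0.0335 to 0.0389, and with limma-voom those of Krt4 and Nkx2-9 were 0.0570 and 0.0514. Where leaving out 1 library put the Sox9-derived side at 0, Krt4 was at least 1178-fold lower (without replicate 2) and Nkx2-9 at least 406-fold lower (without replicate 1), with the same floor. Of the 95 called genes, 10 had 0 fragments in a whole group.

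Genes induced by interferon were lower together in the Sox9-derived organoids. All 20 genes of this list were tested, of which 7 fell, 0 rose and 13 were not called, and 15 fell when adjusted over the list alone. The log2 fold change was below 0 in 18 and above 0 in 2. Usp18, a brake on interferon receptor signalling, fell from 142 ± 26.0 to 0.685 ± 0.277 CPM (log2 fold change −7.70, SE 0.40, edgeR adjusted p = 0.0213). Ifi44 fell from 118 ± 49.3 to 3.56 ± 1.08 CPM (log2 fold change −5.05, edgeR adjusted p = 0.0389), and Ifit1, which binds viral RNA, from 87.04 ± 33.6 to 5.58 ± 0.714 CPM (log2 fold change −3.96, edgeR adjusted p = 0.0406). Bst2, which tethers budding virus to the cell surface, fell from 225 ± 20.4 to 48.4 ± 0.693 CPM (log2 fold change −2.21, edgeR adjusted p = 0.0386). With limma-voom the adjusted p of Ifi44 and Ifit1 was 0.0514 and 0.0533. The other called members were Isg15, Oas1a and Irf9. Reads of Oas1a that match the close paralogs beside it equally well were dropped. The median log2 fold change was −2.82, and camera, a limma test of the list against all other genes, gave an adjusted p of 7.53e-10 with a preset inter-gene correlation. That call was lost at adjusted p = 0.73 with an estimated correlation. Camera then rests on 2 residual degrees of freedom and gave all 20 lists an adjusted p of 0.73 or more. That setting thus singled out no list, and whether it could detect a shifted list was not tested. The preset correlation was assumed rather than estimated. The adjusted p it gave holds only under it, and would be too small if the members vary together more than that. The 7 called interferon genes and the called transcripts of the sex chromosomes divided the 4 libraries in the same way. Both were selected by the same comparison of groups, so this does not link them.

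**Figure D2:**
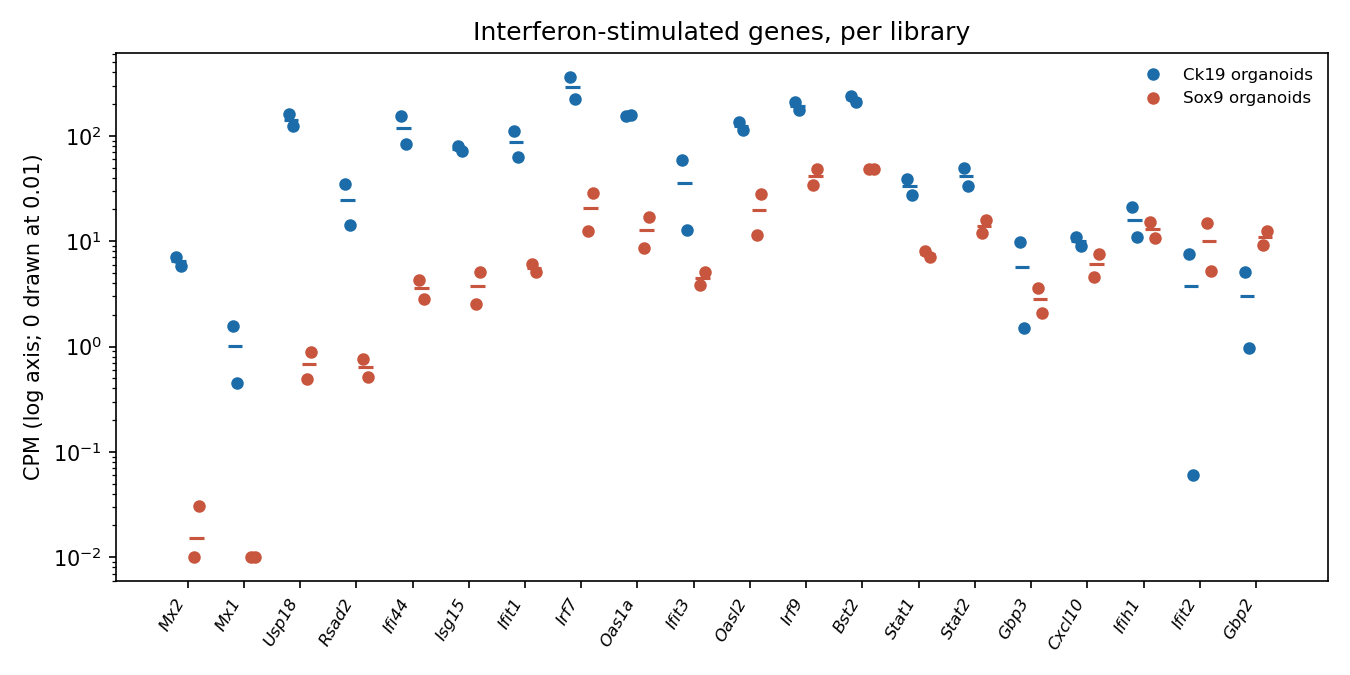
CPM on a log axis of the 20 interferon-stimulated genes, ordered by fold change, with 1 point per library, a bar at each group's mean and values of 0 drawn at 0.01. Usp18, Ifi44, Ifit1 and Bst2 are lower in both Sox9-derived libraries, and the median log2 fold change of the list is −2.82.

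Of the biliary epithelial genes, 25 of 26 were tested. Sox9 and Spp1 rose, Anxa13 fell and 22 were not called, against 5 higher and 1 lower when adjusted over the list alone. Spp1, or osteopontin, a secreted matrix protein abundant in bile ducts (chromosome 5, 104435118 to 104441050), rose from 7584 ± 129 to 20551 ± 3029 CPM (log2 fold change 1.44, SE 0.15, edgeR adjusted p = 0.0467), although 18.8% of its exon bases are shared with a predicted gene. Anxa13, an annexin of polarised epithelium, fell from 260 ± 35.0 to 55.2 ± 11.4 CPM (log2 fold change −2.23, SE 0.23, edgeR adjusted p = 0.0467). The list had a median of 0.21 and was not called by camera (adjusted p = 0.223).

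Targets of E2F in S phase leaned higher in the Sox9-derived organoids as a list, although none of the 28 members was called by edgeR over all genes. The count adjusted over the list alone was 3 higher and 0 lower. The median log2 fold change was 0.42, with 24 members above 0 and camera adjusted p = 0.00436. The call was lost at adjusted p = 0.73 with an estimated correlation, at which camera called no list. Pcna, the sliding clamp of DNA replication, stood at 163 ± 14.9 and 359 ± 18.0 CPM (edgeR adjusted p = 0.0789); it was chosen after its values were seen, as were the other uncalled members named from here on. Without Ck19-derived replicate 1 or Sox9-derived replicate 2 the list's camera adjusted p was 0.0679 and 0.0612. The G2 and mitosis list had a median of 0.48 over 23 members, with no member called and camera adjusted p = 0.108. It was called without Ck19-derived replicate 2 (0.61, adjusted p = 0.0303) or Sox9-derived replicate 1 (0.90, adjusted p = 6.85e-06), and lay at −0.12 without Sox9-derived replicate 2.

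The glycolysis and hypoxia list and the cholesterol synthesis list leaned the other way. In the glycolysis and hypoxia list 0 of 18 members were called over all genes, against 1 higher and 4 lower when adjusted over the list alone. Its median was −0.87 and its camera adjusted p was 0.00549, or adjusted p = 0.73 with an estimated correlation. Bnip3, a mitophagy gene induced by hypoxia, stood at 241 ± 97.3 and 42.1 ± 8.14 CPM, and Ndrg1, another hypoxia gene, at 523 ± 344 and 42.1 ± 0.821 CPM. The glycolytic enzyme gene Eno1 went against the list, at 672 ± 137 and 2074 ± 407 CPM. Reads of Eno1 that match its near-identical copies equally well were dropped. The list's median was −0.29 (adjusted p = 0.233) without Ck19-derived replicate 1, and its adjusted p was 0.0583 without Sox9-derived replicate 2. In the cholesterol synthesis list 0 of 18 members were called, also when adjusted over the list alone. Its median was −0.41 and camera adjusted p = 0.0397, or adjusted p = 0.73 with an estimated correlation. It was not called without Ck19-derived replicate 1 (−0.18, adjusted p = 0.289) or without Sox9-derived replicate 1 or 2 (adjusted p = 0.297 and 0.0612).

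Most markers of other cell types stayed below the count filter. Only 3 of 12 B cell and plasma cell genes passed the count filter (Blk, Fcer2a and Cd79b). Their summed means were 14.0 CPM in the Ck19-derived and 1.01 CPM in the Sox9-derived organoids. None was called over all genes, 3 were lower when adjusted over the list alone, and the median was −3.56 with camera adjusted p = 0.0179, or adjusted p = 0.73 with an estimated correlation. Camera no longer called this list without Ck19-derived replicate 1 (adjusted p = 0.183). The remaining lists of other cell types were not called. The T and NK cell list had 4 tested members (median 0.16, mean −0.34, camera towards higher values, adjusted p = 0.537), the myeloid list 5 (median −0.60, adjusted p = 0.425), the MHC class II list 5 (−0.56, adjusted p = 0.113), the endothelial list 5 (−0.38, adjusted p = 0.383) and the erythroid list 1 (−0.59, adjusted p = 0.425). The mesenchymal and stellate list had 11 tested members and a median of 0.29 (camera adjusted p = 0.425), with 2 higher and 2 lower when adjusted over the list alone. Without Sox9-derived replicate 1 the MHC class II list was called (−1.94, camera adjusted p = 0.0131). Among the myeloid genes Cd14 stood apart, at 1021 ± 37.3 and 1231 ± 137 CPM.

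No member of the remaining liver and signalling lists was called over all genes, and camera called none of these lists. The hepatocyte list had 10 tested members of 27, with 5 on each side of 0, a median of 0.49, a mean of −0.03 and camera adjusted p = 0.929, in the direction of the median. The fetal liver and progenitor list had a median of −0.16 (17 tested members, adjusted p = 0.548) and the bile acid and xenobiotic metabolism list one of −0.85 (7 tested members, adjusted p = 0.425). The medians were 0.22 for the Notch pathway (16 tested members, adjusted p = 0.425), −0.52 for Wnt targets (13 tested members, adjusted p = 0.161) and 0.22 for YAP and TEAD targets (17 tested members, adjusted p = 0.425). The list of immediate early and dissociation stress genes had 19 tested members and a median of −0.41 (adjusted p = 0.425). Adjusted over the list alone, higher and lower members numbered 2 and 2 for hepatocyte, 2 and 1 for fetal liver, 1 and 1 for bile acid, YAP and immediate early genes, 1 and 0 for Notch and 0 and 0 for Wnt targets. For the other uncalled lists these numbers were 0 and 1 for MHC class II genes and 0 and 0 for G2 and mitosis, T and NK cell, myeloid, endothelial and erythroid genes.

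**Figure D3:**
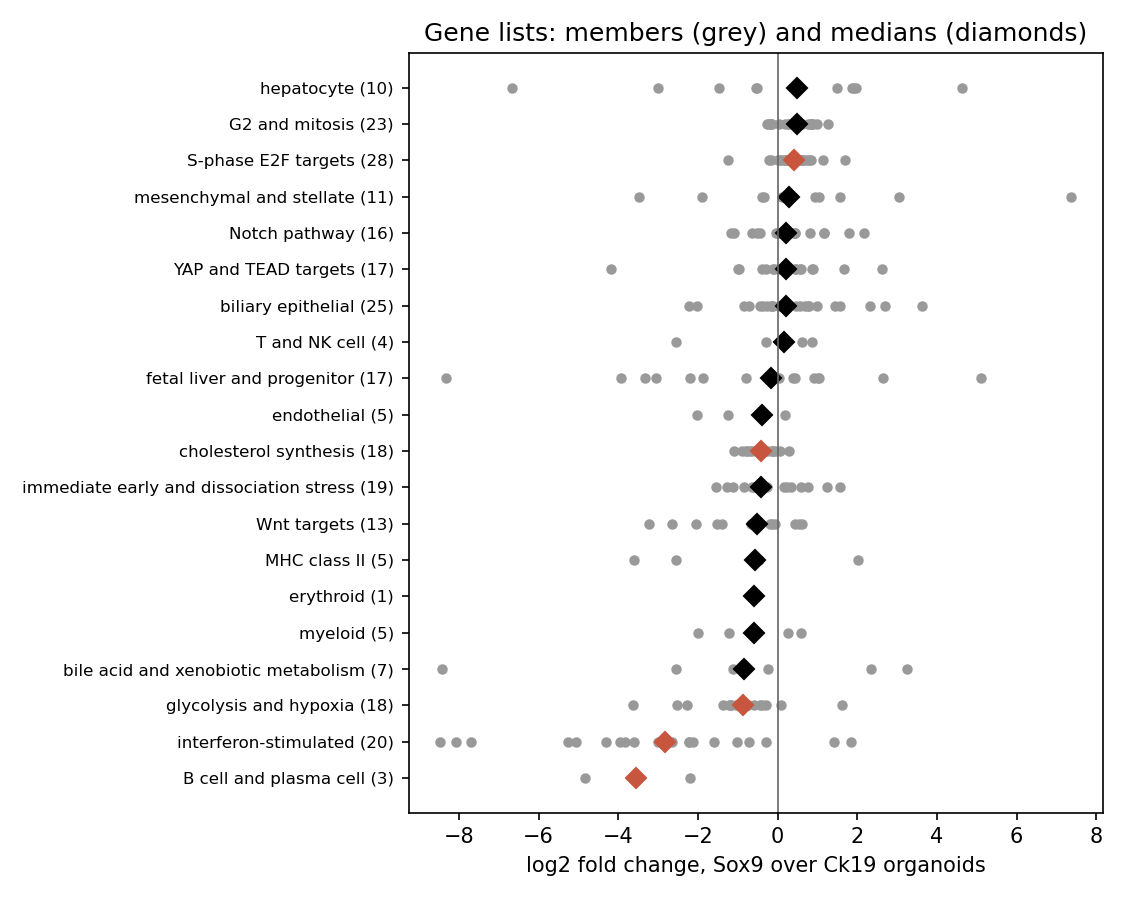
Log2 fold changes (Sox9-derived over Ck19-derived organoids) of the tested members of 20 gene lists as grey points, with the number tested in brackets and the median as a diamond. Red diamonds mark the 5 lists with a camera adjusted p under 0.05 at the preset correlation, from −3.56 for B cell and plasma cell genes to 0.42 for S-phase E2F targets.

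The comparison also depends on which count columns belong to the Sox9-derived samples. A second pair of columns carried the Sox9 name with an added TKO tag that no sample label holds. In its libraries Epcam stood at 8.99 and 5.61 CPM, Krt19 at 0.619 and 1.61 CPM and Alb at 21740 and 13158 CPM. The leukocyte gene Ptprc stood at 14.1 and 15.3 CPM and the globin gene Hbb-bs at 136 and 1250 CPM. These values argue against epithelial organoids like the Ck19-derived pair, but do not say what the tagged libraries were. With that pair in place of the other, an alternative added after the data were seen, edgeR called 5190 genes. Sox9 then had a log2 fold change of 0.70 (edgeR adjusted p = 0.170), Rb1 one of −1.36 (edgeR adjusted p = 0.0496, at 4.5045 and 5.3968 CPM in the tagged pair), Epcam one of −7.48, Krt19 one of −10.20 and Alb one of 10.97, and the interferon list a median of −0.99 (camera adjusted p = 0.0557). Usp18 then had a log2 fold change of −0.55 (edgeR adjusted p = 0.265) and the S-phase list a median of 0.080 (camera adjusted p = 0.97). Both calls were thus lost, in a comparison with libraries of a different mix of cell types. With that pair as an extra group beside the other, edgeR called 14 genes between the Sox9-derived and Ck19-derived organoids, and the adjusted p of Sox9 was 0.0699.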

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

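The count columns that carried the Sox9 name with a TKO tag were used only as alternatives to the Sox9 pair, and they held a strong signal of cell types that were at or near 0 in the organoid libraries. Albumin (Alb) reached 21740 and 13158 CPM in these libraries and the apolipoprotein gene Apoa1 18329 and 15021 CPM. The pan-leukocyte gene Ptprc stood at 14.1 and 15.3 CPM and the adult beta-globin gene Hbb-bs at 136 and 1250 CPM. In the 4 organoid libraries used for the comparison, Apoa1, Ptprc and Hbb-bs each stayed under 1 CPM and Alb under 21 CPM. The values do not assign the TKO-tagged pair to any labelled group, and no biological explanation was tested.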

How the results depend on the processing

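The TKO-tagged pair in place of the Sox9 pair, that pair as an extra group, and the fit without genes on X and Y were chosen after seeing the data. The 95 calls became 97 with relative log expression factors (95 shared), 93 with limma-voom (72 shared) and 87 without genes on X and Y (87 shared). DESeq2 called 1512 (649 higher, 863 lower), no count filter 506 (184 and 322) and the stricter filter 364 (121 and 243), each including all 95, and the cause was not tested. Higher genes were 32.6% of calls in edgeR and 42.9% in DESeq2, and without a filter the median of all genes was −0.21. With the replicate block edgeR called 0 genes, with 2665 at an unadjusted p under 0.05. Deviations of same-numbered libraries correlated at 0.0583 over 2 pairs, so the numbers are not shown to pair samples. Leaving out 1 library gave from 0 to 1394 calls, and the lone library left in a group was then assumed to vary like the other group. The TKO-tagged pair gave 5190 calls in place of the Sox9 pair and 14 as an extra group (13 shared), which adds libraries to the shared spread. A fit of only the groups compared is the fit reported.

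The interferon list lost its call with an estimated correlation, which leaves its median (−2.82) as it was by construction, and had −0.99 with the TKO-tagged pair in place. Its range was −3.33 to −2.33 over fits without 1 library. Of 24 tested named genes, all 24 kept direction and call with relative log expression factors, DESeq2 and no filter. limma-voom kept 18 and lost 5 calls by adjusted p from 0.0514 to 0.0570. The replicate block and leaving out either Ck19-derived library each lost all 17 calls, and the extra group lost 11, while log2 fold changes of those with over 3 fragments in both groups moved by at most 0.12 (block), 0.51 and 0.77 (without replicate 1 or 2) and 0.0130 (extra group). Relative log expression factors kept all 20 lists. The block lost the cholesterol call (adjusted p = 0.0507) and gained G2 and mitosis (0.0246) and MHC class II (0.0340).

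Afp, with both group means under 1 CPM, turned to −1.10 with limma-voom and −0.56 with the replicate block. Without 1 library it ran from −6.28 (a fitted value at 0 fragments, only at least 3.20-fold lower by the floor) to 1.91. Rbl1 ran from −1.17 to 0.16 and Alb from −3.55 to −0.66. Medians ran from −1.17 to 0.32 for bile acid, −1.48 to 0.19 for endothelial, −0.12 to 0.90 for G2 and mitosis, −0.26 to 1.28 for hepatocyte and −0.64 to −0.18 for immediate early genes, whose camera direction turned. They also ran from −1.94 to 0.05 for MHC class II, −1.83 (−1.51 with genes at 0 at their bound) to −0.00028 for fetal liver, −1.01 to 1.37 for mesenchymal, −0.02 to 0.74 for Notch, −0.18 to 0.77 for T and NK cell, 0.077 to 0.54 for YAP, 0.027 to 0.40 for biliary, −0.95 to −0.40 for Wnt, −1.08 to −0.41 for myeloid, −0.93 to −0.30 for erythroid, −4.70 (−2.41 at the bound) to −3.04 for B cell, −1.29 to −0.29 for glycolysis and −0.71 to −0.18 for cholesterol genes. With the TKO-tagged pair in place, the log2 fold change turned for Alb (10.97), Bst2 (0.36), Epcam (−7.48), Krt19 (−10.20), Rbl2 (−0.059), Spp1 (−2.68), Tmeff2 (−11.64) and Wfdc18 (−11.56), the last 2 at 0 fragments and thus only at least 269-fold and 260-fold lower. The direction of the list test also turned for B cell (4.84), bile acid (10.79), biliary (−2.68), cholesterol (−0.063), endothelial (8.06), erythroid (16.05, at the bound 12.90), immediate early (0.15), MHC class II (8.15), myeloid (8.55), Notch (−0.050) and YAP genes (−2.20). As an extra group it turned erythroid (0), hepatocyte (−0.55), mesenchymal (−0.40) and T and NK cell genes (−0.18), all 0 once genes at 0 were held at the floor, and lost the B cell (−2.22, adjusted p = 0.145) and cholesterol calls (0.107). The cause was not tested for any of these. At this depth and n = 2 a 2-fold change was recovered in 16% of simulated genes, which were given no spread in dispersion around the trend.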

Other observations

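Except for the check of single libraries, the depth check, the region check, the even-spread check with all receptor genes and the check of other class I genes, the tests here were chosen after the results were seen, as were the genes named. Some further called genes are given here as values, with no test of a shared theme. Of those lower in the Sox9-derived organoids, Krt5, a basal keratin, stood at 8.39 ± 1.32 CPM (SD, n = 2) against 0.0152 ± 0.0215, the mucin Muc13 at 8.11 ± 0.380 against 0, the microvillus protein Cdhr5 at 32.9 ± 3.02 against 2.24 ± 0.593, and Anxa8 at 224 ± 0.408 against 26.4 ± 2.15 CPM. The homeobox gene Pax9, which starts 80.4 kb from Nkx2-9 on chromosome 12, stood at 25.9 ± 7.86 against 0.0456 ± 0.0644 CPM. The EGF-family growth factor Areg stood at 137 ± 30.6 against 16.7 ± 5.08 CPM. Called genes that were higher in the Sox9-derived organoids included the growth factor receptor Fgfr2 (175 ± 8.26 against 33.7 ± 3.54 CPM), the tendon transcription factor Scx (74.8 ± 4.74 against 15.8 ± 2.45 CPM), the laminin Lama4 (35.4 ± 3.52 against 4.19 ± 0.200 CPM) and the collagen Col16a1 (46.9 ± 7.85 against 5.10 ± 0.959 CPM). In edgeR their adjusted p ran from 0.0261 (Anxa8) to 0.0489 (Krt5 and Muc13).

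Called genes lay near one another more often than random sets of tested genes. Of the 95, 25 had another called gene starting within 250 kb, where 2000 random sets had a median of 4 and at most 17. Without the Y chromosome it was 21 of 91, with a random median of 4 and at most 16. Several of the pairs are members of one gene family, such as Oas1g and Oas1a, Ces2e and Ces2f, Krt5 and Krt4, and Prl2c3 and Prl2c2. Medians of log2 fold change over whole chromosomes lay close together. Over 9481 genes with a mean of at least 10 CPM, they differed from the median of all by −0.22 (chromosome 12) to 0.22 (chromosome 18), where 1 extra copy beside 2 would add 0.58 in every cell.

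Of 3 explanations weighed for the lower interferon list of the Sox9-derived organoids, the first was immune cells mixed into the Ck19-derived cultures. There the 53 T, NK, myeloid, B and plasma cell markers had a median of 0.0763 CPM, under 1% (13.7 CPM) of the 1368 CPM by which the list was higher. That median spans several cell types, so a single admixed type could hardly raise it to the bound. Of the 9 markers above 1 CPM, 5 were lower in the Sox9-derived organoids like the list, namely Cd68 (60.8 against 15.3 CPM), Blk (10.7 against 0.369), Cd79b (2.87 against 0.616), Aif1 (1.89 against 1.25) and Ccl5 (1.49 against 0.252). Cd14 (1022 against 1231), Tcf7, Lck and Csf1r were higher. The abundant leukocyte genes Ptprc, Lyz2 and Ighm stood at 0.109, 0.170 and 0.0314 CPM, which argues against leukocytes as carriers of the 1368 CPM. Immune cells too few to show in these markers were not tested. The marker values are CPM without TMM scaling, the 1368 CPM with it. A single library is argued against too, since the highest median without 1 library was −2.33. Sex or animal of origin cannot be told apart from the group, because 0 groups held libraries with and without Xist. The origin of the cultures, which the design names, and their sex or animal may each account for the difference, and neither was tested.

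The H2 region of chromosome 17 (33 to 38 Mb), which holds the mouse MHC genes, had 4 called genes of 173 tested, 2.31% against 0.552% elsewhere (odds ratio 4.26, 95% interval 1.12 to 11.5, Fisher's exact test, two-sided p = 0.0172, run on the genes that prompted it). Cyp21a1, Gm10499 and Gm8909 were higher and H2-Q6 lower in the Sox9-derived organoids. All 4 have close copies, and reads that match a copy equally well were dropped. The 3 that were higher argue against the lower interferon response as the cause of the whole pattern, not of the lower H2-Q6. The other 14 tested class I genes with an H2 symbol had a median log2 fold change of −1.04, just past the bound of −1. Of these, 10 were below 0 and none was called. Gm10499 and Gm8909 were not counted among them. The smallest edgeR adjusted p values were those of H2-Q4, which was higher (2.53, adjusted p = 0.0507), and H2-Q7, which was lower (−4.25, adjusted p = 0.0640). By that bound the interferon response may play a part for H2-Q6, but the genes moved both ways and the median depends on which are counted. A different H2 haplotype may be involved, but the region's median absolute log2 fold change lay only at the 74.5 percentile of 10000 matched random sets, under the bound of 95 set beforehand. That bound was set wrongly, since a haplotype need change only some of the 173 genes and their median dilutes it, so this explanation cannot be told apart from chance here.

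That more genes had at least 1 fragment in the Ck19-derived libraries is not explained by depth, because a gap of 3406 genes stayed after thinning all libraries to 31883180 fragments. Reads spread evenly over the genome, such as from genomic DNA, could account for it, and fragments outside any feature were 4.003% and 3.68% in the Ck19-derived against 2.89% and 3.13% in the Sox9-derived libraries. Of 1690 olfactory and vomeronasal receptor genes, however, 460 and 426 had a fragment in the Ck19-derived and 158 and 229 in the Sox9-derived libraries, at most 53.2% of the number an even spread would give, under the bound of 80% set beforehand. That bound was set wrongly, since it took all receptor fragments as background, yet 12 and 13 receptor genes of the Ck19-derived libraries had more than 10, where an even spread gives 5.56e-05 and 2.75e-05. In 4 cuts tried after these values were seen the highest share was 59.8% without the top gene, and 73.6%, 80.1% and 88.9% without genes of more than 10, 5 and 3 fragments. Each cut leaves out the genes that depart most from an even spread, so the share rises by construction and the cuts cannot decide. The receptor fragments were thus not all evenly spread, and without genes of more than 10 fragments the share still stayed under 80% in every library. Whether some of the reads were evenly spread stays open, as does a part for the origin of the cultures, which was not tested.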
